A study of Mus musculus with 4 samples.

How the data were processed

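H3K27me3 and H3K4me3 were measured by ChIP-seq in rosette stem cells made from the mouse embryonic stem cell lines CGR8 and R1, in 1 library of each line and mark. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sonicated, and libraries were amplified from the precipitated DNA. The protocol credits both antibodies to the same supplier, while the characteristics of the H3K27me3 samples name another for that antibody, and this was left open. Groups were taken from the labels, with the line as the only replicate within a mark (replicate 1 is CGR8 and replicate 2 is R1). Nothing ties a library to a second culture of its line, so p-values measure only these 4 libraries.

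Each of the 4 lists gives a chromosome, a start, an end and a score for every region, and the authors deposited 1 list per library. Per the submitters' processing notes the tools included Bowtie2 2.0.2, an aligner, SICER 1.1, a caller for broad regions, and bedtools 2.20.1, and the build was mm9. The notes used here give neither their order nor their settings. The control library, if one was used, and the calling threshold are not given in the sources used here. The deposited score has no unit and no stated formula. All starts and ends lie on a grid of 200 bp. The values show that gaps of up to 600 bp were joined for H3K27me3 and of up to 200 bp for H3K4me3, which widens H3K27me3 regions relative to H3K4me3 ones. The lowest deposited scores were 70.6 (CGR8) and 59.4 (R1) for H3K27me3 and 38.5 and 37.3 for H3K4me3, so the lists were not limited at the same value.

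Relative depth was recovered from the scores. In each list, the scores of all regions up to 400 bp long equalled a sum over windows of the negative natural log of a Poisson probability, within 1e-06, for a single mean per window. This held for 8 of 8 regions (CGR8) and 2 of 2 (R1) with H3K27me3 and for 144 of 144 and 155 of 155 with H3K4me3. The next best mean explained 2, 1, 6 and 4 of them. Each candidate mean was solved from 1 of these scores and so explains at least 1 by construction. The R1 H3K27me3 value rests on 2 regions only, which is weak support for it. The mean per window is proportional to the reads used in that library, but the total was not computed, since the effective genome size is not given in the sources used here.

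Starts were counted from 1 and chromosome names kept as in the lists. A region was called shared when it overlapped a region of the other list by at least 1 bp. The share expected by chance came from rotating all regions of a chromosome by a random offset, with the chromosome's length taken as the last position called in any list, in 1000 draws with a fixed seed of 7. Rotation does not keep regions in gene-rich or mappable sequence, so lists that both favour such sequence can exceed this chance level for that reason alone. The p-value is a one-sided permutation p with a smallest value of 0.001, and 0.05 was the threshold. Medians of score and width of regions with the other mark were set against the same rotations, with two-sided permutation p-values. Regions of R1 alone in a block of chromosome 1 were also rotated inside that block. Counts on the X chromosome were compared with Fisher's exact test, two-sided, and counts in that block are described by an odds ratio. The tests were run on simulated lists first, made from the CGR8 H3K27me3 list of 14575 regions. That list was set against lists in which 0%, 10%, 30% or 60% of its regions were kept and the others placed at random. The share came out within 2.35 percentage points of that expected. Of 100 unrelated lists placed at random, 3 had a permutation p of 0.05 or less. Overlap of H3K27me3 with H3K4me3 was not simulated, and random placement does not keep the clustering of real lists. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.

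The regions named by position were set by a rule fixed before the data were examined: the 5 widest regions of each mark found in both lines by mean width, the 5 widest found in a single line for each mark and line, and the 5 longest stretches with both marks in both lines. The block of chromosome 1, the region of the highest score and the mitochondrial regions fall outside that rule and were chosen after their values were seen. The rule for genes needed an annotation on mm9. The gene table used here is on GRCm38.p6, and positions were not converted, so promoter classes, the gene lists fixed beforehand and promoters that differ between lines were not analysed here, and no region is given a gene name.

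The alternatives fixed beforehand were an overlap of at least 50% of the region, the higher-scoring 50% of each list, lists of equal length, autosomes only, regions less than 1000 bp apart merged, regions placed at random on their chromosome in place of rotation, and leaving out either line. Alternatives added after the data were seen left out the block of chromosome 1, also for the X chromosome, or the mitochondrial regions together with the region of the highest score on chromosome 11.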

Results

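Histone marks were mapped by chromatin immunoprecipitation and sequencing in mouse rosette stem cells, pluripotent cells kept in a state between the naive and the primed one. Embryonic stem cells of the lines CGR8 and R1 had been grown for 8 days in N2B27 medium with leukaemia inhibitory factor, 2 µM IWP2, which blocks the secretion of WNT proteins, and 1 µM PD325901, a MEK inhibitor. H3K27me3 is the mark deposited by Polycomb repressive complex 2, and H3K4me3 is found at promoters of active genes and of many silent genes kept ready for activation. Each mark was measured in 1 library of each line, so the 4 libraries fall into an H3K27me3 group and an H3K4me3 group with n = 2 lines each. A difference between CGR8 and R1 therefore has no replicate check within a line. The published naive and primed cells that the series names for comparison were not analysed here. All positions are on mouse build mm9, counted from 1, and the score of a region is the authors' deposited value, used to rank and describe regions within a list. Scores of different lists were set against each other only for regions paired between the lines and for a block of chromosome 1, as ranks, as ratios relative to the rest of the genome, or as a common lower limit.

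H3K27me3 lay in broad regions and H3K4me3 in narrow ones in both lines. The H3K27me3 lists held 14575 regions in CGR8 and 12511 in R1, covering 134.0 Mb and 99.4 Mb. The H3K4me3 lists held 25241 and 24618 regions, covering 59.0 Mb and 55.6 Mb. The median width was 7000 ± 849 bp for H3K27me3 (SD, n = 2) and 2000 bp for H3K4me3 in each line. The widest 10% of H3K27me3 regions began at 15600 bp in CGR8 and 13600 bp in R1, against 4000 bp for H3K4me3 in each. The CGR8 H3K27me3 list covered 1.35 times the length of the R1 list, while the H3K4me3 lists differed by a factor of 1.06. The widths were compared without a test, and an exact permutation test of 2 libraries against 2 could not go below p = 0.333 (two-sided).

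The total read number of each library is not given in the sources used here. The scores of the shortest regions were used to estimate the mean number of reads per 200 bp window that the scoring assumed. It was 2.11 for CGR8 and 1.92 for R1 with H3K27me3, and 0.740 for CGR8 and 0.706 for R1 with H3K4me3. The CGR8 value was 1.097 times the R1 value for H3K27me3 and 1.049 times for H3K4me3. The R1 value for H3K27me3, and with it the ratio of 1.097, rests on 2 regions and is uncertain. A region missing from a list was not called at this depth, which does not show that the mark was absent.

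The first comparison asked where H3K27me3 was most extended in the rosette stem cells and whether both lines carried it at the same places. Each line had 5 H3K27me3 regions of at least 100 kb, and these lay at the same 5 places, each holding H3K4me3 regions. On chromosome 15 a region ran from 102717401 to 102878400 in CGR8 (161 kb) and from 102731801 to 102905000 in R1 (173.2 kb), with 15 H3K4me3 regions inside it in CGR8 and 20 in R1. On chromosome 2 it ran from 74474401 to 74622400 in CGR8 (148 kb, 14 H3K4me3 regions) and from 74475201 to 74620000 in R1 (144.8 kb, 16 regions). On chromosome 6 it ran from 52092201 to 52232800 in CGR8 (140.6 kb, 14 regions) and from 52109201 to 52232200 in R1 (123 kb, 17 regions). On chromosome 11 it ran from 96127801 to 96248400 in CGR8 (120.6 kb, 8 regions) and from 96121601 to 96248800 in R1 (127.2 kb, 12 regions). These 4 places ranked from 2 to 5 by score in both lists, in the same order. The bounds, widths and numbers of H3K4me3 regions inside also depend on where a call was split. On chromosome 6 a further R1 region ran from 52087801 to 52108400, just before the one given. On chromosome 15 a further CGR8 region ran from 102881601 to 102908000, just after the one given. Of the 20 H3K4me3 regions of R1 on chromosome 15, 1 had no CGR8 partner.

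The remaining place, on chromosome 7, was different in make-up. There H3K27me3 ran from 150484401 to 150653400 in CGR8 (169 kb) and from 150572801 to 150682000 in R1 (109.2 kb), with 4 H3K4me3 regions in each line. H3K4me3 covered 4.62% of it in CGR8 and 6.59% in R1, against 13.6% to 21.6% of the regions on chromosomes 15, 2, 6 and 11. Its score ranked 7 in CGR8 and 9 in R1. Inside the H3K27me3 regions of chromosomes 15, 2, 6 and 11, all 51 H3K4me3 regions of CGR8 overlapped one of R1, while 8 of the 65 of R1 had no CGR8 partner, as the map of these regions shows.

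**Figure D1:**
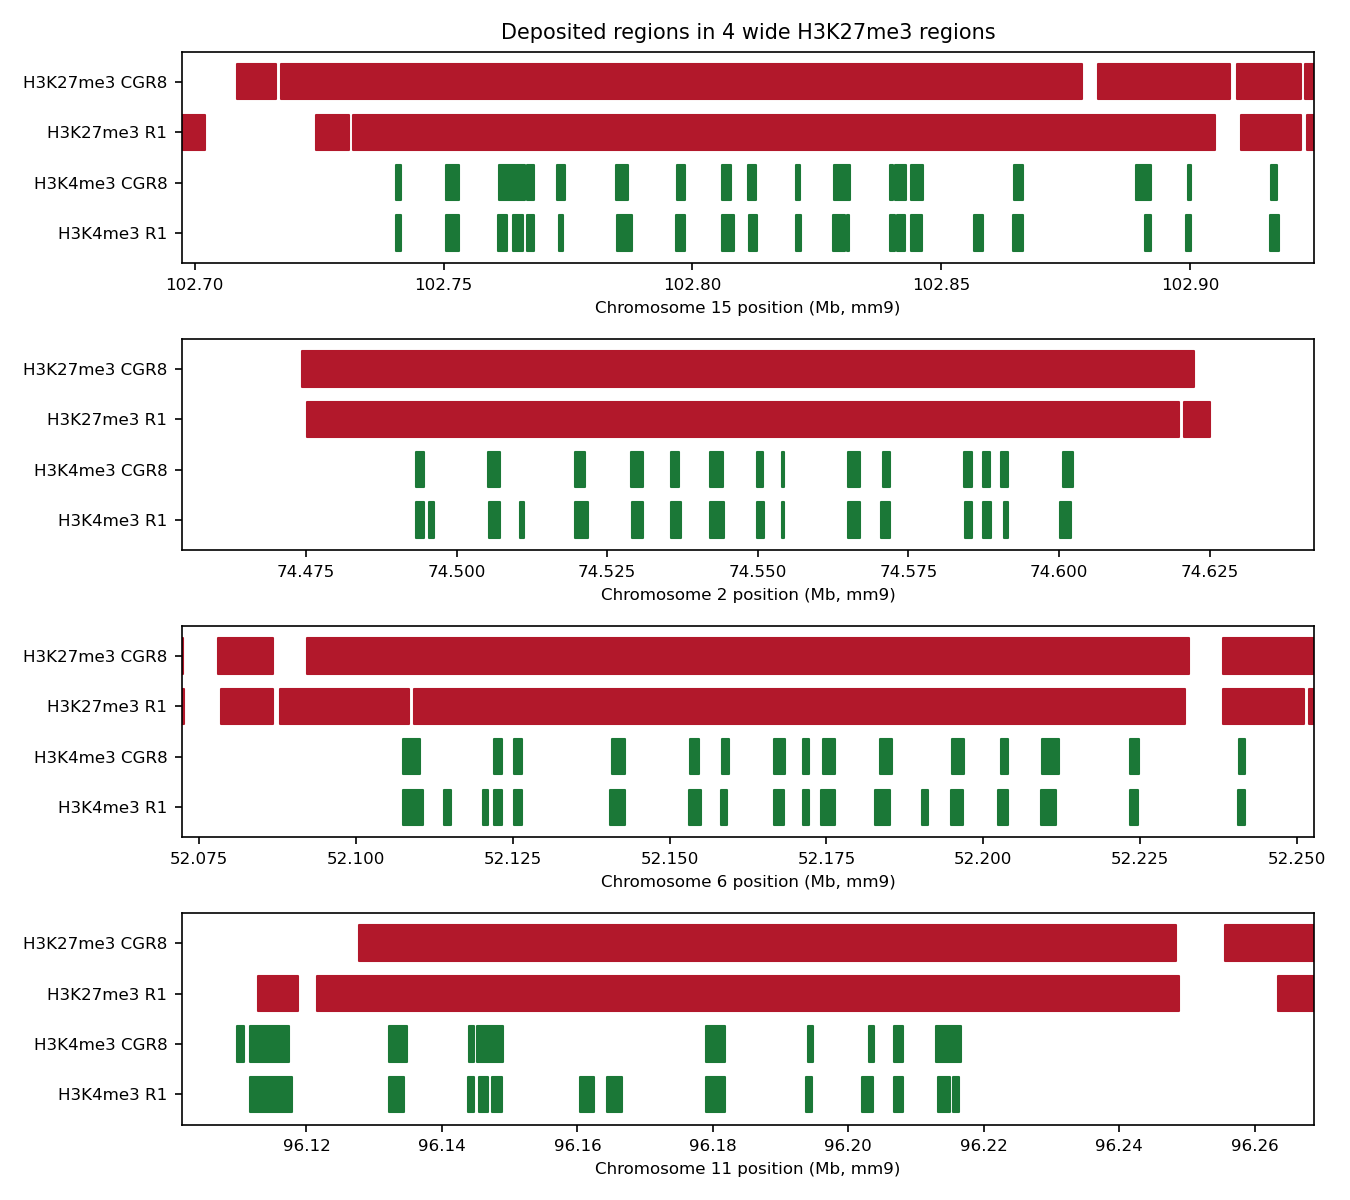
Deposited regions of both marks in both lines at 4 of the 5 widest H3K27me3 places, plotted against position in Mb on mm9, with 1 track for each mark and line and each bar drawn to scale. The widest H3K27me3 region (red) of each track spans 120.6 kb to 173.2 kb, and 8 to 20 H3K4me3 regions (green) lie inside it. Shorter H3K27me3 regions in the same windows are drawn as well.

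Broad H3K27me3 regions were shared between lines more widely than the list as a whole, although a wider region also has more room for an overlap. All 36 regions of at least 50 kb in CGR8 and all 24 in R1 overlapped a region of the other line, and 34 and 22 of them overlapped H3K4me3. At 20 kb and above, 768 of 779 regions in CGR8 and 441 of 449 in R1 were found in the other line. These made up 16.9% of the H3K27me3 cover in CGR8 and 13.2% in R1.

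The next comparison asked how far each mark occupied the same regions in the 2 lines. H3K4me3 regions were shared almost throughout: 22677 of 25241 in CGR8 (89.8%) and 22789 of 24618 in R1 (92.6%) overlapped a region of the other line by at least 1 bp. For H3K27me3 the shares were 9778 of 14575 in CGR8 (67.1%) and 10144 of 12511 in R1 (81.1%). The bases covered in both lines were 74.1% of those covered in either for H3K4me3 and 49.3% for H3K27me3. Over both lists together 91.2% of H3K4me3 regions and 73.6% of H3K27me3 regions were shared, against 4.42% and 8.52% after rotation of the regions along their chromosomes. Both shares lay above all 1000 rotations, with p = 0.001 in the one-sided permutation test, the smallest value these can give. The excess over chance was 20.6-fold for H3K4me3 and 8.64-fold for H3K27me3, and whether the marks differ in it was not tested. It was 39.7-fold and 15.0-fold when at least 50% of a region had to be covered, and 32.2-fold and 13.3-fold in the higher-scoring 50% of each list. The largest fold that can be reached is lower where the chance share is higher, as for H3K27me3.

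Regions found in both lines also ranked alike. Among 21972 H3K4me3 regions with a single partner in the other line, the rank correlation between CGR8 and R1 was 0.977 for the score and 0.885 for the width. Among 8167 such H3K27me3 regions it was 0.823 for the score and 0.676 for the width. These correlations run across regions, which are not independent replicates.

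Regions of a single line stood low in their lists. The 2564 H3K4me3 regions of CGR8 alone had a median score of 49.4, against 468 for shared ones, and the 1829 of R1 alone a median of 46.1, against 462. The 4797 H3K27me3 regions of CGR8 alone had a median score of 90.4, against 188 for shared ones, and the 2367 of R1 alone a median of 74.2, against 142. H3K4me3 overlapped 10.2% of the H3K27me3 regions of CGR8 alone and 56.5% of the shared ones. In R1 these shares were 23.6% and 54.7%. Shared regions were also wider, with a median of 8200 bp against 6800 bp in CGR8 and 6800 bp against 5600 bp in R1. Overlap with H3K4me3 rose with score, and regions of equal score were not compared, so these shares do not link it to being shared. With each list divided by score into 10 classes of equal size, the share of H3K27me3 regions found in the other line went from 29.2% in the lowest class to 99.9% in the highest for CGR8 and from 53.2% to 100% for R1.

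**Figure D2:**
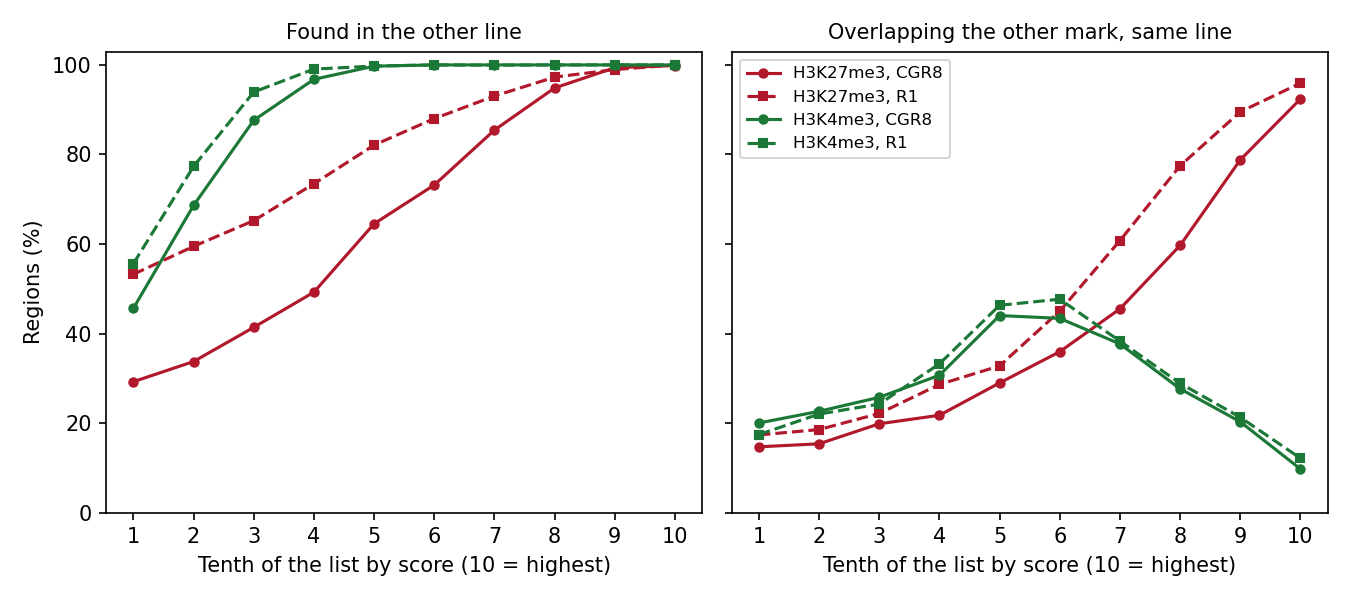
Share of regions in percent, for each of 10 equal classes of a list by deposited score, that overlapped a region of the same mark in the other line (left) or of the other mark in the same line (right), with a point for each class, mark and line. H3K27me3 regions overlapped H3K4me3 more often toward the top of the list (92.4% in CGR8 and 95.9% in R1), while H3K4me3 regions overlapped H3K27me3 most often in the middle of it.

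The widest H3K27me3 region of CGR8 alone lay on chromosome 16 from 35478601 to 35520600 (42 kb, score 906), and the next on chromosome 8 from 12148601 to 12179800 (31.2 kb, score 488). Others lay on chromosome 3 from 79221801 to 79249600 (27.8 kb), on chromosome 7 from 133190601 to 133216800 (26.2 kb) and on chromosome 10 from 120246401 to 120271800 (25.4 kb). The 5 widest of R1 alone, 23.6 kb to 28.6 kb long, all lay on chromosome 1. They ran from 104955801 to 104979400, from 105711201 to 105739800, from 109253401 to 109277400, from 111528001 to 111552600 and from 121094201 to 121122800. The widest H3K4me3 region of a single line was 7.0 kb in CGR8, on chromosome 5 from 134911601 to 134918600, and 4.8 kb in R1, on chromosome 5 from 143018201 to 143023000.

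The R1 regions of chromosome 1 belonged to a block of 20 Mb, from 104 to 124 Mb, with 565 H3K27me3 regions in R1 and 34 in CGR8. All 34 CGR8 regions there overlapped an R1 region, and 530 of the R1 regions had no CGR8 partner. Called H3K27me3 regions covered 4.55 Mb of the block in R1 and 0.310 Mb in CGR8. The 65 H3K4me3 regions paired between the lines there also scored higher in R1, with a median log2 score ratio of 1.043 (R1 over CGR8). Extra copies of the block in R1 are therefore a candidate explanation, taken up further below, and the counts alone do not show a gain of H3K27me3. On the rest of chromosome 1 the order was the other way round, with 698 regions in R1 and 888 in CGR8. Without the block, 84.6% of R1 regions and 67.0% of CGR8 regions were shared.

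**Figure D3:**
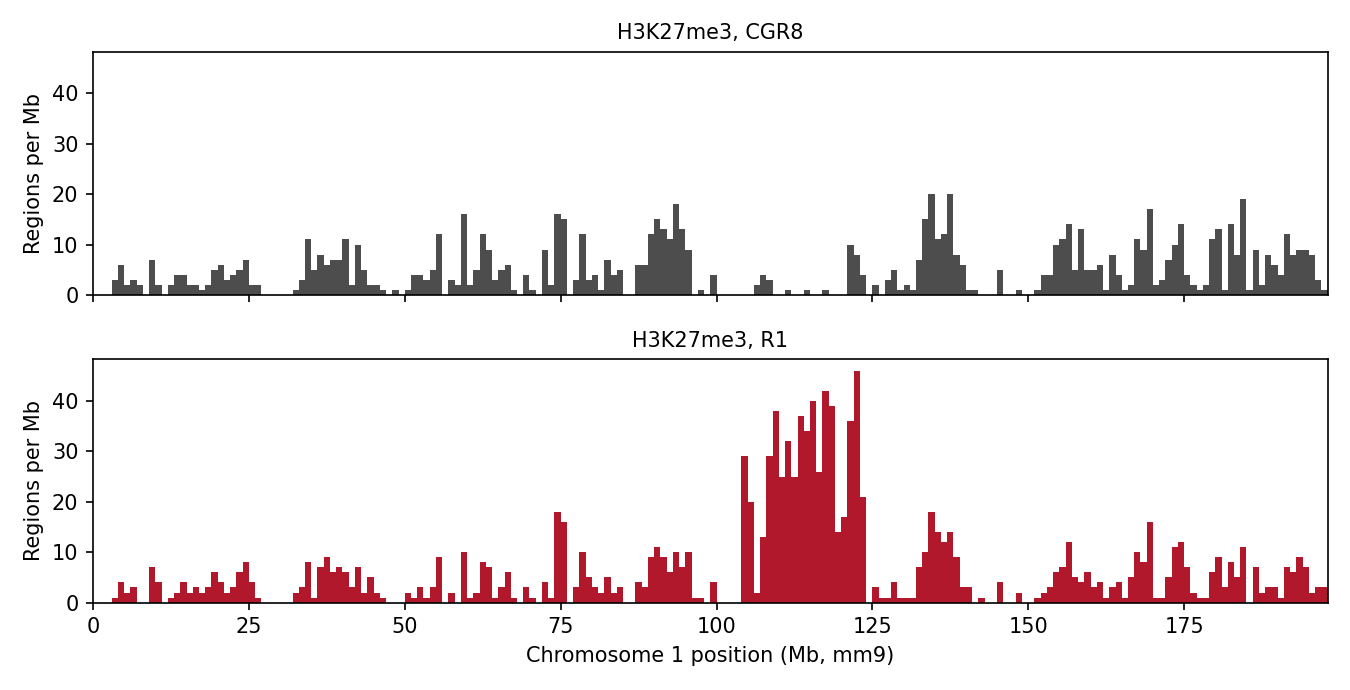
Number of H3K27me3 regions starting in each Mb of chromosome 1 (mm9) in CGR8 (upper) and R1 (lower), on the same scale, a bar for each Mb. From 104 to 124 Mb R1 had 565 regions and CGR8 had 34. These counts do not show whether the mark or the number of copies of this part differed.

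The comparison of the marks within a line asked how often the Polycomb mark and the promoter mark lay together in the rosette stem cells. In CGR8, 6018 of 14575 H3K27me3 regions (41.3%) overlapped an H3K4me3 region of the same line, and in R1 6107 of 12511 (48.8%), a mean of 45.1% ± 5.32 (SD, n = 2). In the other direction, 7113 of 25241 H3K4me3 regions in CGR8 (28.2%) and 7176 of 24618 in R1 (29.1%) overlapped H3K27me3, a mean of 28.7% ± 0.685 (SD, n = 2). Rotation of the regions gave 9.99% and 8.75% for H3K27me3 and 6.65% and 5.01% for H3K4me3. The overlap was thus 4.13-fold and 5.58-fold above the rotated share for H3K27me3, in CGR8 and R1. For H3K4me3 it was 4.24-fold and 5.82-fold above it. Rotation takes no account of gene density or mappability, so these values do not measure a link between the marks alone. Each of the 4 shares lay above all rotations of its list (one-sided permutation test, p = 0.001).

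Overlap meant that narrow H3K4me3 regions lay inside broader H3K27me3 regions. Where at least 50% of an H3K27me3 region had to be covered by H3K4me3, the mean share fell to 3.75%, while the mean share of H3K4me3 regions covered to that extent by H3K27me3 was 25.7%. With the H3K4me3 list shortened by score to the length of the H3K27me3 list, 29.0% of H3K27me3 regions overlapped H3K4me3.

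H3K27me3 regions with H3K4me3 had higher scores than those without it. The median score was 255 against 104 in CGR8 and 228 against 84.6 in R1, and the score per kb was 30.8 against 15.9 and 32.4 against 15.2. Broader regions meet others more often by chance, and regions that met H3K4me3 after rotation had a median score of 170 in CGR8 and 160 in R1. The observed medians were higher in each line (two-sided permutation test by rotation, p = 0.002, the smallest it can give). The median width of H3K27me3 regions with H3K4me3 was 8600 bp in CGR8, below the 9022 bp after rotation (permutation p = 0.028), and 7400 bp in R1, where it did not differ from the 7774 bp after rotation at the threshold of 0.05 (permutation p = 0.076). The mean ratio of median scores was 2.57, and 1.03 with at least 50% of the H3K27me3 region covered, a rule that narrow regions meet more easily, while scores rose with width (rank correlation across regions 0.691 in CGR8 and 0.698 in R1).

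H3K4me3 regions with H3K27me3 were narrower than the others. Their median width was 1600 bp in both lines, against 2200 bp for the rest in CGR8 and 2000 bp in R1, and it lay below all rotated medians (two-sided permutation test, p = 0.002 in each line). They were most frequent in the middle of the H3K4me3 lists, at 44.0% of score class 5 of 10 in CGR8 and 47.7% of class 6 in R1. In the highest class they made up 9.74% in CGR8 and 12.1% in R1. Their median score was 321 in CGR8, against 342 for H3K4me3 regions without H3K27me3, and lay below the 412 after rotation (permutation p = 0.010). In R1 it was 374, against 350 for regions without H3K27me3 and 460 after rotation (permutation p = 0.072). Their score per kb was 197 against 165 in CGR8 and 222 against 176 in R1, and it did not differ from rotation at the threshold of 0.05 in either line (permutation p = 0.783 and 0.655).

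Called regions of both marks covered the same bases in both lines at 6308 stretches, 9.28 Mb in all, with a median length of 1400 bp. Joined gaps count as covered, and the lists do not show whether both marks lay in the same cells. When only the higher-scoring part of each list was used (50%), 2585 stretches were found. The longest lay on chromosome 18 from 83078201 to 83086800 (8.6 kb), followed by chromosome 11 from 23974201 to 23982600 (8.4 kb) and chromosome 2 from 172371001 to 172379400 (8.4 kb). The next were on chromosome 4 from 99319601 to 99327800 (8.2 kb) and on chromosome 2 from 146659201 to 146666400 (7.2 kb). The H3K27me3 regions holding these 5 stretches were 8.6 kb to 27 kb wide, so none of the stretches lay in the regions above 100 kb. Bases with both marks made up 8.74% of the H3K27me3 cover in CGR8 and 11.96% in R1, and 19.9% and 21.4% of the H3K4me3 cover.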

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

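The bounds of the block on chromosome 1, the tests of the calling threshold and of depth there, the rank shift and the rotation inside the block and the alternatives that leave out regions were chosen after the results were seen.

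The block of chromosome 1 from 104 to 124 Mb stood out because R1 had 565 of its 12511 H3K27me3 regions in it and CGR8 34 of 14575, an odds ratio of 20.23 that only describes these lists, since the bounds were drawn around the R1 regions, neighbouring regions are not independent and each line has 1 library. The lowest score was lower in R1 (59.4 against 70.6), but with R1 regions below 70.6 left out the block still held 437 R1 regions, 12.85 times the CGR8 number. The mean number of reads per window in R1 was 0.9115 times that of CGR8. It argues only weakly against greater depth in R1, since it rests on 2 R1 regions. More copies of the block in the R1 cells would raise the other mark as well, and the 65 H3K4me3 regions paired between the lines there had a median log2 score ratio of 1.043 (R1 over CGR8), against at most 0.38 in 20558 runs of as many neighbouring pairs elsewhere, and a median rank shift of 14.9 percentile points, against at most 5.24. A candidate explanation is therefore a gain of this part of chromosome 1 in the R1 culture, with reads from extra copies called as H3K27me3 regions. H3K4me3 overlapped 4.72% of the 530 regions of R1 alone in the block, against 4.11% after rotation inside it (two-sided permutation p = 0.713) and 29.0% of the regions of R1 alone outside it, but a true spread of H3K27me3 in R1 stays open, since no input library was analysed here.

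H3K27me3 regions found in a single line numbered 4797 of 14575 in CGR8 and 2367 of 12511 in R1. Whether the greater length of the CGR8 list accounts for this gap was left open. Outside the block and at equal length, 25.1% of CGR8 regions and 21.1% of R1 regions had no partner. These shares were 4.001 percentage points apart, within the bound set beforehand. Most shared regions have a single partner, so lists cut to equal length give near-equal shares whatever the cause. The comparison therefore cannot decide the question. Weak regions near the calling threshold may account for many of the regions found in a single line, but whether for nearly all was left open. With the block left out, 90.52% of the higher-scoring 50% of regions in CGR8 and 98.1% in R1 were found in the full list of the other line. The lower share falls between the bounds set beforehand (90% and 95%). A difference in H3K27me3 between the lines themselves was not tested, as each line has 1 library.

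The H3K27me3 region with the highest score lay at the start of chromosome 11, from 3026801 to 3100200 in CGR8 and from 3027001 to 3100200 in R1. Its score was 2.86 times the second highest in CGR8 and 2.39 times in R1. Reads that gather at this sequence with either antibody would be a candidate explanation. H3K4me3 regions covered 45.2% of it in CGR8 and 42.08% in R1, between the bounds of 25% and 50% set beforehand, and the best of these ranked 115 and 28 by score among all H3K4me3 regions, so the explanation stays open. No biological explanation was tested.

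Regions were also called on the mitochondrial chromosome, which carries no nucleosomes. There were 2 in each list, covering 12 kb for H3K27me3 in CGR8, 12 kb for H3K4me3 in CGR8, 11.8 kb for H3K27me3 in R1 and 10.2 kb for H3K4me3 in R1. Their best score ranked 28 and 38 in the H3K27me3 lists of CGR8 and R1, and 9529 and 14186 in the H3K4me3 lists.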

How the results depend on the processing

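The alternatives without the block of chromosome 1 and without the mitochondrial and highest-scoring chromosome 11 regions were added after the data were seen. The shares of shared regions and of regions overlapping the other mark stayed above chance in every alternative run (permutation p = 0.001 throughout), but their size moved. Shared H3K4me3 regions ranged from 90.2% to 96.6% and shared H3K27me3 regions from 68.6% (at least 50% covered) to 78.8% (higher-scoring 50% of each list), with 75.0% without the block. H3K27me3 regions overlapping H3K4me3 were 48.8% without CGR8 and 41.3% without R1, 41.8% in the higher-scoring 50%, 29.0% at equal list length and 3.75% at 50% coverage, since H3K4me3 regions are too narrow to cover most H3K27me3 regions. H3K4me3 regions overlapping H3K27me3 ranged from 23.5% to 29.9%. In the higher-scoring 50% of the lists, which holds fewer regions by construction, stretches with both marks in both lines numbered 2585 in place of 6308. There, 589 H3K4me3 regions of CGR8 and 267 of R1 had no partner in the same part of the other list. For H3K27me3 these numbers were 2002 and 869. They are not counts of regions of a single line. Against the full other list, 100% of H3K4me3 regions in each of score classes 6 to 10 had a partner in CGR8, and 99.96% to 100% in R1. The median H3K27me3 width was 6400 bp to 7600 bp with either line left out and 7200 bp after merging. The same merging left the median H3K4me3 width at 2000 bp. With gaps joined alike in both marks, H3K27me3 regions were thus still the wider ones. Alternatives for promoter windows, start sites and gene lists were not run, as no mm9 annotation was used here. Of the lowest 10% of H3K27me3 regions by score in CGR8, 29.2% were found in the other line, and whether depth sets this was not tested.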

Other observations

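The comparison of the X chromosome with the autosomes and the count of wide H3K4me3 regions were chosen after the data were seen.

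H3K27me3 regions were sparse on the X chromosome in both lines relative to H3K4me3 regions. CGR8 had 138 H3K27me3 and 647 H3K4me3 regions on the X, which is 21.3 H3K27me3 regions per 100 H3K4me3 regions, against 58.7 on the autosomes, where single chromosomes ranged from 44.8 to 78.1. R1 had 150 and 636, which is 23.6 per 100 against 51.5, with autosomes from 38.2 to 92.9. The highest of these is chromosome 1, which holds the block from 104 to 124 Mb, and without the block the R1 autosomes had 49.4 per 100 and ranged from 38.2 to 59.0. The odds ratio was 0.363 in CGR8 (Fisher's exact test, p = 5.09e-32) and 0.458 in R1 (Fisher's exact test, p = 5.26e-20). In the higher-scoring 50% of each list it was 0.401 and 0.513, and without the block 0.363 and 0.478. Neighbouring regions are not independent, so these p-values describe the lists only. The scores assumed a single mean per window in each list. The number of copies of the X therefore also bears on which regions were called, and this was not tested. Among the regions that were called, the median score of H3K27me3 regions on the X was close to that on autosomes, at 136 against 132 in CGR8 and 116 against 116 in R1. For H3K4me3 it was 297 against 334 and 322 against 366. Only called regions have a score, so these medians cannot show whether the signal on the X as a whole was lower. The Y chromosome held 3 H3K4me3 regions in each line and no H3K27me3 region in either list.

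The 5 widest H3K4me3 regions found in both lines did not overlap H3K27me3, while some other wide ones did. On chromosome 2 a region from 162875601 to 162894400 was 18.8 kb wide in CGR8 and 19 kb in R1, and on chromosome 15 a region from 25680201 to 25700600 was 20.4 kb wide in CGR8 and 16.2 kb in R1. The others among the 5 widest lay on chromosome 13 from 23514201 to 23531200, chromosome 16 from 22396601 to 22415000 and chromosome 8 from 44376601 to 44397000 in CGR8. Of H3K4me3 regions at least 5 kb wide, 154 of 1457 in CGR8 (10.6%) and 175 of 1221 in R1 (14.3%) overlapped H3K27me3, against 28.2% and 29.1% of all H3K4me3 regions, although wide regions have more room to meet another. At 10 kb and above the overlap was 11 of 88 in CGR8 (12.5%) and 10 of 67 in R1 (14.9%). Of the regions at least 5 kb wide, 1451 of 1457 in CGR8 and 1221 of 1221 in R1 were found in the other line.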
